A study of Mus musculus with 12 samples.

How the data were processed

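RNA of wild-type mouse autopods of stage E12.5 was hybridised to Affymetrix MOE430 A and B GeneChips, 12 arrays in all, from 3 forelimb and 3 hindlimb samples. Samples were grouped by the tissue named in the labels and are called by the number in their titles. For 1 A array, forelimb 11, the tissue label names the autopod without the limb. It was placed with the forelimb by the letter its title shares with the other forelimb titles, so among the labels its limb rests on the title alone. Its Tbx5 signals were 474 and 1145.1 on 2 probe sets, where the hindlimb samples had 8.0 to 13.9 and 29.3 to 173.8. The same number on an A and a B array was read as the same numbered sample.

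The deposited values are intensities, MAS5.0 signals per probe set on a linear scale, per the labels; the note on MAS5.0 is missing for forelimb 11 on the A array. The 2% trimmed mean was 350.1 on every A array and 70.0 on every B array, so the authors' values had been scaled to one target within each design. Detection calls, scanner settings and the software version are not given in the sources used here. Gene symbols came from the platform annotation and were updated through gene identifiers with a RefSeq gene table of GRCm38.p6, used for names only. On the A array 20393 probe sets had 1 symbol, 691 several and 1606 none (20364 were found in the gene table); on the B array these were 14674, 245, 7656 and 14499. Probe sets with several symbols or none were tested and not named.

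Each array was brought to a 2% trimmed mean of 500, which multiplied the A arrays by 1.43 and the B arrays by 7.14, and values were taken as log2(signal + 32). This stretches dim B signals: the probe sets on both designs put the scaled B array at a factor of 0.312 from the A scale, so the filter is laxer on the B array and levels were not compared across designs. Probe sets with a scaled signal of at least 100 on at least 3 of the 6 arrays were kept, and the 64 control probe sets of each design were left out. Hindlimb was compared with forelimb within each design by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided, Benjamini-Hochberg adjustment within a design, threshold 0.05). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision; the median standard error was 0.16 on the A array and 0.23 on the B array.

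Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested genes (21 on the A array, 11 on the B array) were tested by camera with a preset correlation of 0.01, with an estimated correlation as an alternative, and by fry, using the brightest probe set of each gene over the 6 arrays. Lists too small for this are given as values. The rule named every tested limb identity gene and sex-linked gene. It named up to 10 genes per direction on the A array and 5 on the B array past the threshold with limbs that did not overlap, filled up to 5 by p where fewer passed. From each list it named at most 4 members past the threshold, or else the 2 of smallest p. Ratios of 3' to 5' signals were compared by exact permutation tests.

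The alternatives were pseudocounts of 1 and 100, no filter, a filter at 200, quantile normalization, values as deposited, no trend, array weights, a block of consecutive sample numbers, adjustment over both designs, one probe set per gene, a minimum change of 1.5-fold and leaving out each sample. The fit was tested on simulated data for the hindlimb and forelimb comparison, with 200 changed probe sets per design and noise drawn from limma's own variance prior. Of 50 probe sets per fold size on the A array (15338 run), 18% were recovered at 1.5-fold, 82% at 2-fold and 100% at 4-fold, with 5 false calls among 155. On the B array (17145 run) these were 4%, 22% and 72%, with 10 false calls among 106. With so many changed probe sets the adjusted threshold was looser than in the real data, where 5 and 2 passed. The simulated noise was also independent between probe sets. The shares are thus not the power of the real comparison.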

Results

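Gene expression was measured in the autopods, the hand and foot plates, of wild-type mouse embryos of stage E12.5. There were 3 forelimb samples (numbered 11, 13 and 25) and 3 hindlimb samples (12, 14 and 26), each hybridised to the A and the B design of the Affymetrix MOE430 GeneChip set, 12 arrays in all. The A design carried 22690 probe sets and the B design 22575. After scaling, 65.6% to 68.1% of probe sets on the A arrays and 72.7% to 75.5% on the B arrays had a signal of at least 100, and 15338 and 17145 probe sets were tested. The comparison asks which transcripts differ between fore and hind autopods. All differences are log2 hindlimb minus forelimb on the log2(signal + 32) scale, which understates the change of dim probe sets, with n = 3 samples per limb. Nothing in the labels says that the samples were separate animals or pools, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

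The clearest differences lay in the transcription factors known to mark limb type. Tbx5, a T-box factor of the forelimb, was lower in hindlimb by both of its probe sets, with differences of -3.65 ± 0.18 (SE, limma adjusted p = 7.75e-06) and -3.83 ± 0.38 (adjusted p = 0.00441). On the first, the scaled Tbx5 signal was 474 to 555 in the forelimb samples and 8.0 to 13.9 in the hindlimb samples. As the hindlimb signals lie below the pseudocount, the size of the difference depends on it, from -5.49 with a pseudocount of 1 to -2.45 with 100. On the second, hindlimb 14 had a signal of 174 against 29.3 and 29.7 in the other hindlimb samples, and the forelimb samples had 1145 to 1381. Pitx1, a homeobox factor of the hindlimb, was higher in hindlimb by 1.95 ± 0.19 (adjusted p = 0.00441) and 1.69 ± 0.20 (adjusted p = 0.0193) on its 2 probe sets. With a sample left out, the second Pitx1 probe set stayed past the threshold in 1 of 6 fits. With the filter also re-applied to the 5 arrays left, it passed in 0, the first Pitx1 probe set in 5 and the second Tbx5 probe set in 4; the first Tbx5 probe set passed in 3 and failed the filter in 3. Without the signal filter neither Pitx1 probe set passed, nor the second of Tbx5. Tbx4, the hindlimb counterpart of Tbx5, was higher by 1.99 ± 0.13 on the B array (adjusted p = 0.000167, 0.0874 without the trend in the variance prior), with signals of 1124 to 1251 in forelimb and 4497 to 5558 in hindlimb. The Tbx4 probe set on the A array gave 1.33 ± 0.18 and missed the threshold (adjusted p = 0.0514). It passed with a filter at 200, quantile normalization, values as deposited or array weights. With the filter kept from all arrays it also passed without hindlimb 12, but with no other sample left out. All 3 samples of one limb lay above all 3 of the other on each of these probe sets.

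The other genes fixed as markers of limb identity did not pass over all probe sets. Hoxc10, a posterior Hox gene, had a difference of 1.08 ± 0.24 (limma adjusted p = 0.555). Its signals were 213 to 409 in forelimb and 637 to 791 in hindlimb. Adjusted over the 2 hindlimb identity genes tested on the B array alone, its limma p was 0.000848. Hoxc9 (-0.04), Hoxc6 (-0.04 and 0.08) and Hoxc5 (-0.05) lay near 0. The sign of Hoxc9 turned when any 1 of 4 samples was left out, and that of Hoxc5 turned under quantile normalization. Isl1, known from the early hindlimb field, was below the signal filter on both of its probe sets, with mean signals of 33.4 and 8.2 in forelimb and 71.2 and 53.2 in hindlimb.

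**Figure D1:**
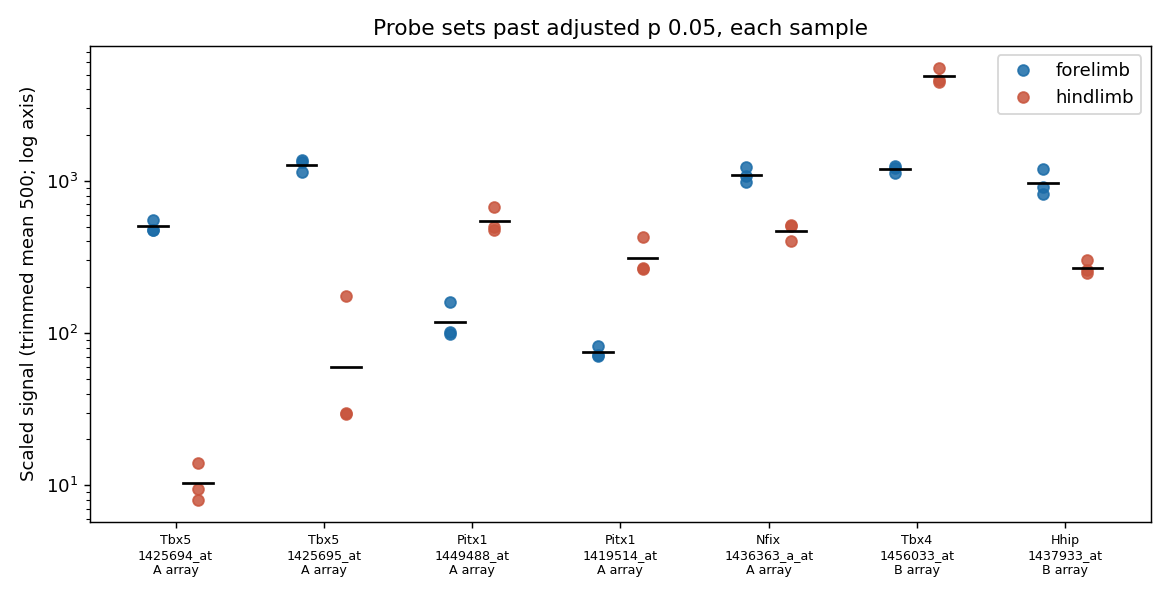
Scaled signal (log axis) of each sample for the 7 probe sets past an adjusted p of 0.05, with forelimb samples in blue and hindlimb samples in red. Points are samples and bars are means taken on the log2(signal + 32) scale; on Tbx5 the first probe set has hindlimb signals of 8.0 to 13.9.

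On the A array, 5 probe sets of 3 genes passed an adjusted p of 0.05 in limma, 2 of them higher in hindlimb (Pitx1) and 3 higher in forelimb (Tbx5 and Nfix). Nfix, a nuclear factor I transcription factor, was lower in hindlimb by -1.17 ± 0.14 (adjusted p = 0.0211), with signals of 985 to 1225 in forelimb and 399.7 to 513 in hindlimb. The other Nfix probe sets gave -0.96 (adjusted p = 0.104) and -1.03 (adjusted p = 0.147). Next by p, and not past the threshold, stood Krt15, a basal keratin (-1.38 ± 0.20, adjusted p = 0.059), Id4 (-0.86 ± 0.14, adjusted p = 0.104) and Htra1, a secreted protease (-1.45 ± 0.24, adjusted p = 0.104). In the other direction the Tbx4 probe set given above came first. Frzb, a secreted Wnt antagonist (1.02 ± 0.18), Snrnp40 (0.73 ± 0.14) and Pmaip1, a pro-apoptotic factor (0.90 ± 0.17), followed with adjusted p of 0.183 to 0.189. Other probe sets differed for Snrnp40 (0.065 at like brightness), Htra1 (-0.40 on a brighter one), Id4 (-0.41 and -0.27) and Frzb (0.80, limbs overlapping). At an unadjusted p under 0.05 there were 850 probe sets, 284 higher in hindlimb and 566 higher in forelimb, where chance alone would give 767. Other groupings of the 6 samples into 3 and 3 gave 327 to 1339. The limbs did not overlap on 11.04% of the tested probe sets, against 10% by chance. The 5 calls fell to 3 without forelimb 11, 13 or 25 or hindlimb 14 or 26 and rose to 9 without hindlimb 12, with the filter kept from all 6 arrays. With it re-applied to the arrays left there were 1, 2 and 0 calls without forelimb 11, 13 and 25, and 8, 3 and 3 without hindlimb 12, 14 and 26. Nfix was kept in 1 of 6 fits either way. Without the trend in the variance prior Nfix did not pass, and 4 calls were left. Without the signal filter 1 probe set passed, with array weights 14.

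On the B array, Tbx4 and Hhip were the 2 probe sets past the threshold. Hhip, a hedgehog-binding protein of the cell surface, was lower in hindlimb by -1.73 ± 0.19 (limma adjusted p = 0.0214), with signals of 824 to 1191 in forelimb and 246 to 304 in hindlimb. A second Hhip probe set on this array gave -2.49 (adjusted p = 0.0664), and the probe set on the A array gave -1.34 (adjusted p = 0.104). Values next in order, none past the threshold, were higher in hindlimb for Fbxo41 (1.74), Meak7 (1.59), Sapcd2 (1.53) and Bves (1.79). They were lower for Zdbf2 (-0.91), Cryzl1 (-2.40), Abcc10 (-1.80) and Egfr, the epidermal growth factor receptor (-0.83). For 4 of these, other probe sets did not show the change: Cryzl1 gave 0.15 and -0.03 on the B array and -0.17 on the A array, Bves -0.15 on the A array, Fbxo41 -0.01, and Sapcd2 0.11 and 0.07. Egfr gave 0.27 on another B probe set and -0.65, -0.34, -0.33, -0.10 and -0.02 on the A array. At an unadjusted p under 0.05 there were 949 probe sets, 399 higher in hindlimb and 550 higher in forelimb, against 857 by chance, and 10.9% did not overlap. Other groupings of the 6 samples gave 568 to 1064. Without the trend in the variance prior neither probe set passed, and without the filter Tbx4 alone did. Leaving out forelimb 11 or 25 or hindlimb 14 or 26 left 1 call, Tbx4. Hhip was lost as well without forelimb 13, where Tbx4 and Cryzl1 passed, and was kept in 1 of these 6 fits, that without hindlimb 12 (4 calls).

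**Figure D2:**
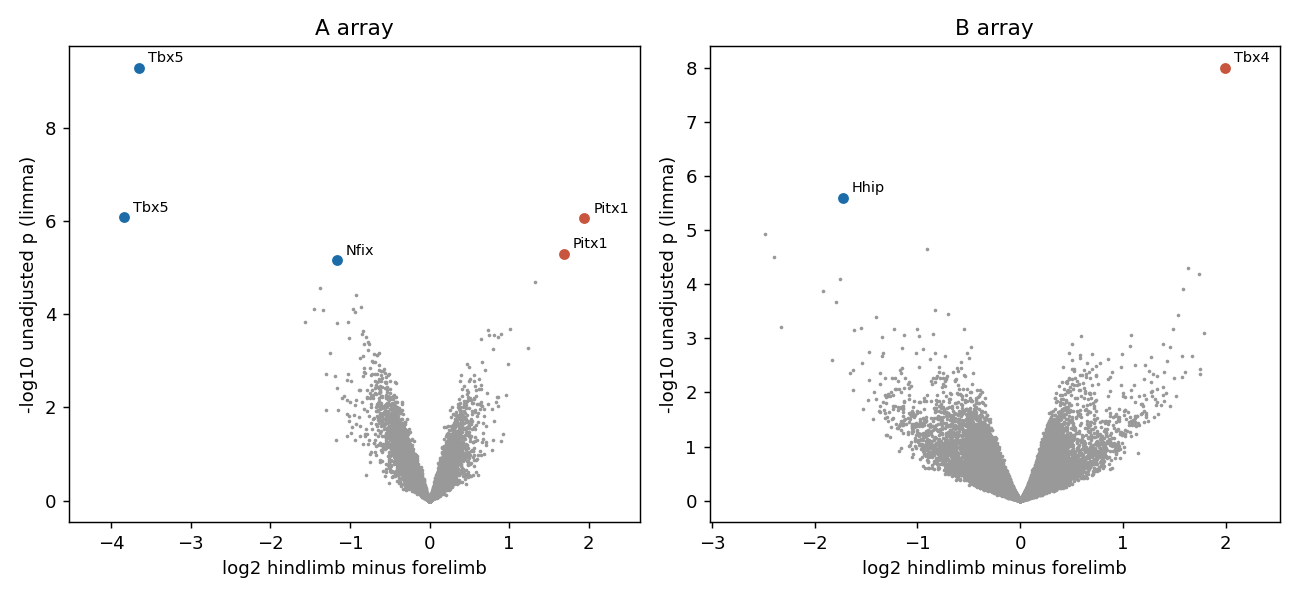
Difference between limbs (x axis, log2 hindlimb minus forelimb) against -log10 of the unadjusted limma p (y axis) for each tested probe set of the A array (15338) and the B array (17145). Coloured points passed an adjusted p of 0.05: red higher in hindlimb, blue higher in forelimb.

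Gene lists of the skeletal and connective tissue lineages were lower in hindlimb on the A array by camera with a preset correlation. With an estimated correlation none of the 4 lists of this paragraph passed (adjusted p = 0.117 for tendon, cartilage and joint, 0.208 for muscle). The Gapdh log2 ratio of 3' to 5' signal, a sign of RNA quality, also parted the limbs on the A array (-0.239 to -0.078 in forelimb, -0.299 to -0.263 in hindlimb, exact p = 0.1), the array of every list that passed. It did not on the B array (exact p = 0.8), where 0 lists passed. The B lists held fewer genes, and their medians were also negative for tendon (6 genes, -0.296), joint (5 genes, -0.235) and cartilage (9 genes, -0.025). The contrast between the designs thus cannot decide on RNA quality. The beta-actin ratio went the other way on the A array, with overlapping limbs (0.172 on average in forelimb, 0.243 in hindlimb, exact p = 0.3). Of 16 tested tendon genes 15 had a negative difference, with a median of -0.32 (camera adjusted p = 1.46e-07), and of 21 cartilage genes 16 did, with a median of -0.33 (adjusted p = 1.56e-07). No member of either list passed over all probe sets, while 8 tendon and 9 cartilage genes passed when adjusted over the list alone. Values included Col1a1 (-0.83 ± 0.15), a fibrillar collagen chain, and Tnc (-0.98 ± 0.25), the matrix glycoprotein tenascin C, in the tendon list. In the cartilage list they included Matn4 (-0.79 ± 0.15), a matrilin, and Acan (-0.72 ± 0.16), the core protein of the main cartilage proteoglycan. Not all members moved so. Scx of the tendon list had -0.101 (0.073 on the B array), and Mkx had -0.105 on the B array. In the cartilage list Sox9 had -0.314. The 5 positive values there were Col9a1 (0.192), Foxa2 (0.164), Hapln1 (0.072), Sox6 (0.067) and Sox5 (0.058). The lists thus do not show a shift of whole lineages. The joint interzone list (10 genes, median -0.23) was lower with an adjusted p of 0.00637, with 2 members past over the list alone. Gdf5, a growth factor of forming joints, had -0.60 ± 0.15 and Osr1 had -0.84 ± 0.18. Of 15 muscle genes 14 were negative (median -0.21, adjusted p = 0.00508), and 0 passed over the list alone. Mef2c had -0.58 and Des, the filament protein desmin, -0.21 on the probe set in the list test and -0.95 on a dimmer one, with overlapping limbs on each. The muscle list also lost its call without forelimb 11 (mean -0.15 against -0.24, camera adjusted p = 0.142) or hindlimb 12 (mean -0.17, adjusted p = 0.0519), and the joint list without hindlimb 12 (adjusted p = 0.0519). By fry, which asks only whether a list moves one way, tendon had an adjusted p of 0.044 and cartilage 0.0433, joint interzone 0.0735 and muscle 0.174.

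Markers of the surface ectoderm, another tissue of the autopod, were lower as well by camera with the preset correlation (20 genes, median -0.24, 15 negative, adjusted p = 0.000359). They were not past the threshold with an estimated correlation (adjusted p = 0.117) or by fry (adjusted p = 0.0528). Of these genes 5 were past over the list alone, with Krt15 at -1.38 and Krt14, a basal keratin, at -0.83 (-0.66 and 0.08 on its other probe sets). Other members did not fall: Epcam (-0.013), Cdh1 (0.013) and Trp63 (0.089) lay near 0, and Krt8 (0.276) and Krt18 (0.305) were higher. The list thus does not show less ectoderm as a whole. None of the next 5 lists passed with an estimated correlation, where the adjusted p was 0.117 for the BMP, proximal and Wnt lists, 0.141 for early response and 0.145 for retinoic acid. The interdigit and BMP list had 18 of 21 negative values (median -0.12, adjusted p = 0.00128; 3 past over the list alone), with Id4 at -0.86 and Bmp7 at -0.56. Proximal limb and TALE factors (7 of 8 negative, median -0.25, adjusted p = 0.00637) included Irx5 at -0.54, and 0 passed over the list alone; Emx2 of the same list had -0.61 on the B array. The Wnt pathway list had 24 of 30 negative values (median -0.14, adjusted p = 0.0168), although the 1 member past over the list alone, Frzb, went the other way. Early response and dissociation stress genes had a median of -0.21 (19 genes, adjusted p = 0.038), with Ccn2 at -0.64 and Klf4 at -0.48, and 0 past over the list alone. The retinoic acid list (14 genes, adjusted p = 0.0404) had a median of -0.03 and a mean of -0.18, with Rdh10, an enzyme of retinoic acid synthesis, at -1.01 and past over the list alone. Rarb, a receptor, had -0.83 with overlapping limbs, as hindlimb 12 (509.7) was like the forelimb and hindlimb 14 and 26 had 211.8 and 209.5. By fry the BMP (adjusted p = 0.0264) and proximal (0.0433) lists passed, and Wnt and early response (0.0684 each) and retinoic acid (0.142) did not. The early response list kept its call in only 8 of the 15 other settings; its mean of -0.16 became -0.07 with a filter at 200 (camera adjusted p = 0.603) and -0.10 without hindlimb 12 (adjusted p = 0.409). Retinoic acid kept it in 9 of 15 (adjusted p = 0.159 without hindlimb 26) and Wnt in 12 of 15 (up to 0.0697).

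The Hox clusters went in different directions by camera with the preset correlation, but neither passed with an estimated correlation (adjusted p = 0.117 for Hoxa and 0.217 for Hoxd) or by fry (0.126 and 0.25). Hoxa genes were higher in hindlimb (5 of 6 positive, median 0.18, camera adjusted p = 0.00637), with Hoxa9 at 0.51 ± 0.13 and Hoxa5 at 0.54 ± 0.20, and 1 passed over the list alone. Another Hoxa9 probe set gave 0.18 with overlapping limbs, and Hoxa5 on the B array gave -0.17, forelimb above. Hoxd genes were lower (5 of 6 negative, median -0.25, adjusted p = 0.0119), with Hoxd11 at -0.43 ± 0.14 and Hoxd9 at -0.44 ± 0.15, and 2 passed over the list alone. The Hoxd call was also lost without forelimb 25 (mean -0.15 against -0.22, camera adjusted p = 0.0668), hindlimb 12 (mean -0.13, adjusted p = 0.136) or hindlimb 26 (mean -0.17, adjusted p = 0.0713), while without hindlimb 14 the mean was -0.36. The Hoxa call was lost without hindlimb 14 (adjusted p = 0.0616). Too few Hoxb and Hoxc genes were above the filter on either array for a list test; the smallest p values belonged to Hoxb3 (-0.31) and Hoxb4 (-0.29, limbs overlapping), and to Hoxc10 (1.08) and Hoxc13 (-0.46). Cell cycle genes were slightly higher (22 of 33 positive, median 0.05, camera adjusted p = 0.0143; adjusted p = 0.126 with an estimated correlation and 0.117 by fry), with Bub1, a mitotic checkpoint kinase, at 0.27 and Ccnf at 0.32, and 0 past over the list alone. This call was lost in 3 of 15 other settings (adjusted p up to 0.115).

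The other 8 lists of the A array did not pass camera. Their adjusted p was 0.067 for the hedgehog and the FGF lists (Spry1 -0.55, and Spred2 -0.51 on the B array with overlapping limbs, where others of its probe sets gave -0.40 and 0.53), 0.072 for erythroid genes (median 0.10, Hbb-y 0.18, with 0.06 and -0.05 on its other probe sets, Hbb-bh1 0.32 with overlapping limbs) and 0.144 for ephrins and semaphorins (Sema3c -0.55, Sema3e -1.04). It was 0.617 for endothelium (Aplnr 0.46; Flt1 -0.34, with 0.33 on another probe set and 0.19 on the B array), 0.852 for macrophages and leukocytes (Lcp1 0.001, with 0.33 on a dimmer probe set, Coro1a 0.26), and 0.986 for both hypoxia (Hk1 0.20 and Vegfa -0.22, with 0.53 and -0.35 on dimmer probe sets) and nerve (Ngfr -0.72, Nefm 0.72). On the B array 0 of the 11 lists large enough passed; the lowest adjusted p was 0.383, shared by the joint, cartilage, tendon, ephrin and Wnt lists (Rspo3 of the last at 0.67), and at an unadjusted p under 0.05 camera gave none and fry gave 1, the joint interzone list. The mixed form of fry, which counts changes in either direction, passed among these lists for nerve on the A array (adjusted p = 0.00354). On the B array it passed for hedgehog (adjusted p = 0.0267). Hhip was the 1 list member past over all probe sets of the B array outside the identity lists. Of the 13 lists past on the A array, 8 passed without hindlimb 12.

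**Figure D3:**
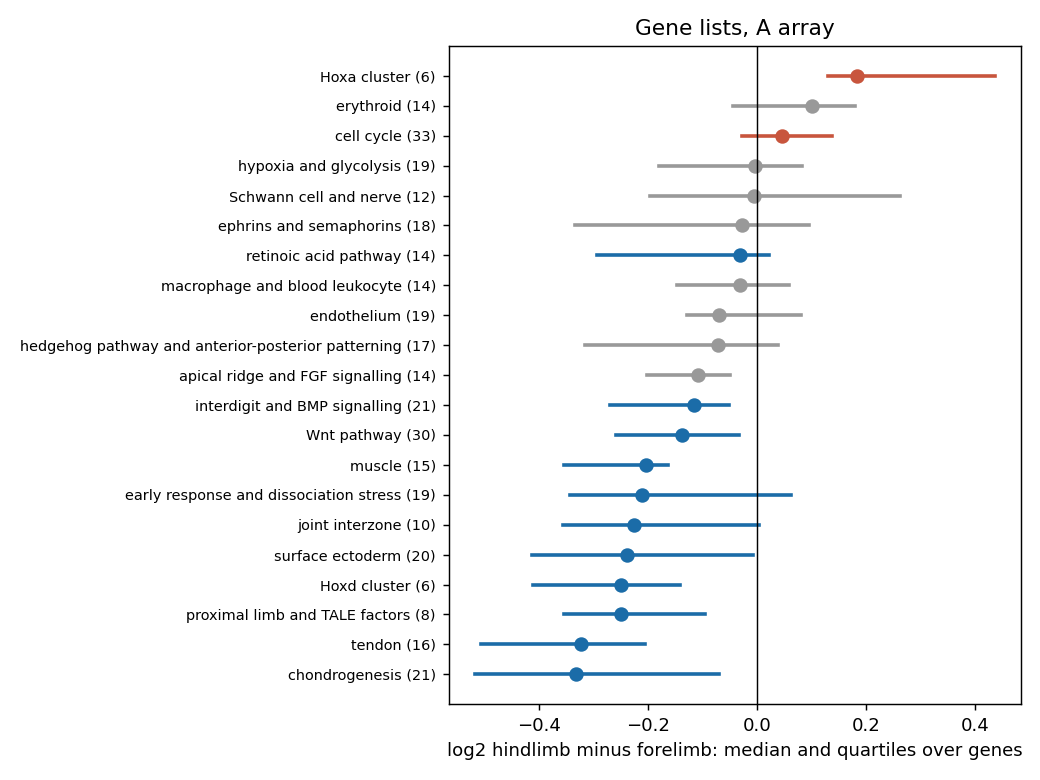
Median (point) and quartiles (line) of log2 hindlimb minus forelimb over the genes of each of the 21 lists tested on the A array, with the number of genes in brackets. Coloured lists passed camera with a preset correlation, blue lower and red higher in hindlimb; the cartilage list has the lowest median at -0.33.

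The 100 probe sets that both designs carry gave differences that correlated across probe sets (Pearson r = 0.60, Spearman rho = 0.571), with 78% of the same sign; probe sets are not independent replicates, and 0 of them passed the threshold on either array. Each of the 6 samples on the A array matched the array of its own number on the B design best (r of 0.409 to 0.674 over these probe sets, highest with another number 0.283). Differences between the samples alone can thus give a correlation between the designs. No other split was tried on these probe sets. As measures of RNA quality, the log2 ratio of 3' to 5' signal of Gapdh was -0.18 ± 0.09 (SD, n = 3) in forelimb and -0.28 ± 0.02 in hindlimb on the A array, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples can give. On the B array it was -0.16 ± 0.09 and -0.14 ± 0.03 (exact p = 0.8). The beta-actin ratio differed by 0.07 on the A array (exact p = 0.3) and -0.01 on the B array (exact p = 0.9). None of the sex-linked probe sets passed in limma, or reached an unadjusted p under 0.05; Eif2s3y differed by 0.45 ± 0.39 (adjusted p = 0.967), Kdm5d by 0.33 and 0.09, Uty by 0.07 to 0.37 and Xist by -0.51 to -0.06. Forelimb 13 had the lowest signal on each of the 7 Y-linked probe sets, and without it the differences of Uty and Kdm5d turned negative.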

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

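The test on Xist was chosen after the values had been seen; the comparison with probe sets of like level was set before its result was seen. Control probe sets for 18S ribosomal RNA lie outside the comparisons and gave a high signal in 1 sample. Forelimb 11 had an 18S 3' signal of 502 on the A array, where the other samples had 105 to 138, and of 1401 on the B array, where they had 299 to 570. What raised it stays open, and no explanation was tested. Without forelimb 11 the A array gave 3 calls and the B array 1.

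Forelimb 13 had the lowest signal on each of 7 Y-linked probe sets, with a median deviation of -1.27 on the log2 scale from the median of the other samples. Probe sets of like level had a median deviation of -0.033 there, so signals of that level were not lower in general after scaling. As all arrays had been scaled to one trimmed mean, this cannot tell whether the array was dim before scaling. A smaller share of male embryos in that sample could also raise Xist, and stays open. Forelimb 13 was highest on 2 of 3 Xist probe sets (10224 on the brightest, the others 3983 to 7444), but on the other it had 1503.7, below forelimb 11 (2050.2) and hindlimb 12 (2015.4). Hindlimb 14 was next lowest on the Y-linked probe sets (median deviation -0.4) and next highest on the brightest Xist probe set. It was lowest on the other Xist probe sets (479.9 and 93.4). Whether samples were pools is not stated in the labels. Xist and Y-linked signals occurred in the same samples: outside forelimb 13, a Kdm5d probe set had 202.4 to 336.2.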

How the results depend on the processing

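The alternatives were planned except for the B array on the A array's scale, added after seeing the data. Leaving out each sample was planned, but not its filter: a first run re-applied it to the 5 arrays left, and keeping it from all 6 was chosen after those values were seen. With the filter kept, the dimmer Tbx5 probe set passed in 9 of 9 settings and all 6 leave-outs, and Tbx4 on the B array in 9 of 10 and all 6. The brighter Tbx5 and Pitx1 probe sets passed in 8 of 9 and all 6, the dimmer Pitx1 in 8 of 9 and 1 of 6, Nfix in 7 of 9 and 1 of 6, and Hhip in 8 of 10 and 1 of 6. The 5 calls on the A array became 1 without the filter, 14 with array weights and 3 to 9 with a sample left out. With the filter re-applied they were 0 to 8, the lowest without forelimb 25. The leave-outs passed were then 6 of 6 for Tbx4, 5 for the brighter Pitx1, 4 for the brighter Tbx5, 3 for the dimmer Tbx5, 1 each for Nfix and Hhip, and 0 for the dimmer Pitx1. By construction the dimmer Tbx5 probe set fails that filter once a forelimb sample is gone, and the dimmer Pitx1 once a hindlimb sample is. The 2 calls on the B array became 1 without the filter, 0 without the trend, 5 on the A array's scale and 1 to 4 with a sample left out under either filter. The count of limb identity probe sets went from 5 to 2 without the filter. Lists past on the A array went from 13 to 0 with an estimated correlation and 8 to 14 with a sample left out. A correlation above the preset 0.01 does not account for every loss. With an estimated correlation, camera also judges its statistic by the residual degrees of freedom of the 6 arrays. The preset form uses the number of genes instead. A lost call thus does not by itself mean correlated genes. The cell cycle list had an estimated correlation of 0.01, and its unadjusted camera p rose from 0.00682 to 0.0541. For the BMP list the estimate was -0.021, and the unadjusted camera p rose from 0.000244 to 0.0159. At the filter of 200 the muscle list gave no value. Array weights added the other 2 Nfix probe sets. Otherwise the cause was not tested.

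Consecutive numbers were tried as a replicate block, which gave 8 calls on the A array (the 5 with Hmga2, Rdh10 and Krt15) and 4 on the B array (with Cryzl1 and another Hhip probe set). Deviations of consecutive samples correlated at 0.208, 0.108 and 0.076 on the A array and 0.002, 0.048 and 0.039 on the B array. These values are low and the labels name no pairs, so the fit without pairs was kept. On the A array each forelimb sample correlated best with its consecutive number, on the B array 2 of 3 did. The mean log2 signal of the Y-linked probe sets was lowest in forelimb 13 (6.753) and, among hindlimb samples, in hindlimb 14 (7.448). Pairs are thus not ruled out.

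Signs turned only in values far from the threshold. Hoxc5 became 0.013 under quantile normalization, and with array weights the brightest Xist probe set became 0.012 and a Uty probe set on the B array -0.039. With a sample left out, Hoxc9 ranged from -0.426 to 0.181 and Hoxc5 from -0.159 to 0.059. Uty ranged from -0.222 to 0.39 and -0.079 to 0.568 on the A array and from -0.098 to 0.618 and -0.737 to 0.691 on the B array. Kdm5d ranged from -0.111 to 0.663 and -0.187 to 0.283, and Xist from -0.912 to 0.088 and -0.394 to 0.283. Dim probe sets limit the rest: a fold of a signal near 32 is damped by the pseudocount.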

Other observations

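The genes in the next 2 paragraphs were chosen after their values were seen. Hmga2, a chromatin protein known from growing embryonic tissue, was higher in hindlimb on 3 A probe sets (0.75, 0.48 and 0.49, limma adjusted p = 0.189 to 0.496) and 1 B probe set (0.63, adjusted p = 0.775). With consecutive numbers as a block, 1 Hmga2 probe set passed.

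Of the genes measured by different probe sets on the 2 designs (2558), 156 had an unadjusted p under 0.05 on the A array, and 71.8% of these had the same sign on the B array. The other 9 splits of the samples gave 50.9% to 70%, so a shared sign arises also from the samples themselves. Both designs reached an unadjusted p under 0.05 for 32 genes with the same sign, where the other splits had at most 13, and for 3 with opposite signs (Pick1, Col1a2 and Dbh). Besides Tbx4 and Hhip, the 32 included Rdh10 (-1.01 and -0.84), Slit2 (-0.69 and -0.59), Sema3e (-1.04 and -0.73), Tnc (-0.98 and -1.07), Tbx18 (-0.66 and -0.40) and Chrdl1 (0.65 and 0.996). Col1a2, of the same collagen as Col1a1, had -0.34 on the A array and 0.57 on the B array, so its probe sets do not give one direction.

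Tests were chosen after the result was seen for the splits and the dissection level; the test on maturation genes was set before their values were seen, and that on RNA quality before its slope was, though the ratios and lists had been. With 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split gave 5 calls on the A array (highest other 2; 1 split as large), 2 on the B array (highest other 1; 1 split as large), 13 lists on the A array (highest other 3; 1 split as large) and 0 lists on the B array, as did all 10 splits. At an unadjusted p under 0.05 on the A array, the split of forelimb 11 with hindlimb 12 and 26 gave 1339 probe sets, above the 850 of the limbs. Other splits gave 1059 and 927 there, and on the B array splits gave 1064 and 974, above the 949 of the limbs.

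Cartilage, tendon and ectoderm lists were lower in hindlimb on the A array, as was the Gapdh ratio, while the beta-actin ratio was higher (0.172 in forelimb, 0.243 in hindlimb). A difference in RNA quality could move these lists. Within limbs their mean had a slope of 0.31 ± 0.67 (SE) on the Gapdh ratio, and 0.431 ± 3.77 without forelimb 13, so this cause stays open. A more distal cut of the hindlimb could lower these lists. The mean of 4 proximal genes minus that of Hoxa13 and Hoxd13 differed by 0.16 ± 0.22, which decides nothing. The proximal limb and TALE list was lower in hindlimb, the direction such a cut would give (camera adjusted p = 0.00637, 0.117 with an estimated correlation). Of the 4 proximal genes, Shox2 (0.364) and Hoxa11 (0.201) were higher and Meis2 (-0.291) and Meis1 (-0.109) lower, so the cut stays open. A less advanced hindlimb is a candidate biological explanation; 6 tested genes known to fall as embryos mature had a mean difference of 0.052 ± 0.126, which leaves it open too. Hmga2, another such gene, was left out because its higher values in hindlimb (0.48 to 0.75), the direction this explanation needs, had been seen. As the lists' calls were also lost when camera estimated the correlation, a less advanced hindlimb remains a hypothesis.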
